A study of Homo sapiens with 30 samples.

How the data were processed

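Total RNA of H9 cells, isolated with Trizol and labelled as biotin cRNA, was hybridised to 30 Illumina expression bead arrays. The labels place the arrays in 10 groups of 3 biological replicates, namely day 1, day 3, and NSB and PIP at days 5, 7, 9 and 11. The design text names an HT-12 array, whereas the 48701 probes of the deposited tables carry the names of an earlier bead array probe set, so probes were matched by the identifiers in the files alone. Apart from the bound on folds, the alternatives called added and the genes said to be named after their values were seen, the choices below were made before the data were examined.

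Per the file headers, the deposited unnormalised table holds for each probe and array a mean bead intensity, a detection p-value, a number of beads and a standard error of the bead brightness. The authors made it in GenomeStudio, with no version stated, and its intensity values are neither background-subtracted nor normalized. The deposited processed values are intensities on a linear scale. Set against the unnormalised table they have the same ranks within each array, nearly the same median on every array (6.44 to 6.52) and 35.0% to 35.2% of values below 0, which are the marks of background subtraction and quantile normalization. Median bead numbers per probe were 37 to 40. The median standard deviation between replicates was 0.123 on the log2 scale and the median bead standard error 0.0556, over 9376 genes detected on all 30 arrays. By group, the median standard deviation between replicates was lowest at day 3 (0.0710) and highest in NSB at day 7 (0.151). The arrays of day 3, NSB day 5 and PIP day 5 each carry a pair of sample codes, and these groups had the 3 lowest values (0.0710, 0.0930 and 0.0889). If the codes stand for pooled samples, which the labels do not state, the spread of these groups is not that of single samples. The number of arrays limits the precision, and 0 pairs of arrays were identical.

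Unnormalised intensities were corrected for background with the normexp model, using the detection p-values in place of control probes, raised by an offset of 16, quantile normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Of 23687 probes with 1 gene name, 23651 had an Entrez identifier found in the human RefSeq annotation, used for names only, and 0 symbols were changed. Left out of the gene tests were 24979 probes with no gene name and 35 with several. Probes with a detection p-value under 0.05 on at least 3 arrays were kept, which left 21500 probes, 15495 of them with 1 gene name. Each gene was represented by its probe with the highest mean over the 30 arrays, giving 13488 genes tested, 1613 of which had at least 2 probes past the filter. Opposite calls by another probe of the same gene occurred for 12 of these genes in PIP against NSB at day 11, and for 175 in NSB day 11 against day 3.

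A linear model with a mean for each of the 10 groups was fitted in limma over all 30 arrays, with 20 residual degrees of freedom and empirical Bayes moderation (6.95 prior degrees of freedom). Comparisons were day 3 against day 1, day 11 against day 3 in each arm, PIP against NSB at days 5, 7, 9 and 11, and the change of the PIP against NSB difference from day 5 to day 11. Moderated tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Both day 11 against day 3 comparisons share the day 3 arrays, so they were not set against each other. Replicate numbers were not taken as pairs, and the mean correlation of residuals was -0.009 between arrays with the same number and 0.005 between others. Lower bounds on folds set each array of the dimmer group to at least the lowest normalized value among the probes detected on that array. Where a probe was detected on no array of that group, its bound is given as "at least".

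Lists of genes fixed beforehand numbered 26, with 405 different genes. They were pluripotency, preplacodal and placode, non-neural ectoderm and border, lens, pituitary placode, sensory placode neurogenesis, anterior neural ectoderm, neural progenitor, neural crest, neuronal differentiation, epidermis, simple epithelial keratins and junctions, trophoblast and amnion, mesendoderm, mesenchyme and fibroblast, endothelium and blood, BMP targets, Nodal and activin targets, WNT targets, FGF and ERK targets, Notch targets and ligands, Hedgehog targets, retinoic acid and HOX, cell cycle, hypoxia and glycolysis, and stress and apoptosis. Of their genes 297 were tested, 77 were below the filter and 31 were not analysed here. Lists with at least 3 measured genes were tested with camera in limma at a preset correlation of 0.01, with adjustment over the 182 tests of 7 comparisons. Calls were also made with an estimated correlation, and with fry, which tests whether the genes of a list move on balance 1 way and does not compare them with other genes.

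Named genes followed a rule. At day 11 of PIP against NSB they were the 10 largest rises and 10 largest falls among called genes with no overlap between the groups and with the probe detected on all 3 arrays of the higher group, and 5 and 5 elsewhere. Added were up to 4 called members of each list with the largest change and a panel of 20 developmental genes. Genes known only by a clone or reading frame name, and genes of the sex chromosomes used to type cells, were counted and not named. Genes of the day 9 comparison, of a further trophoblast list, and NR2F1 and CXCR4 were named after their values were seen.

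Alternatives fixed beforehand were array weights, no normexp correction, scaling to the array median, no filter, a stricter filter (detection p-value under 0.01 on all 3 arrays of a group), the mean of a gene's probes, replicate number as a block, only the arrays compared, leaving out each array, the deposited processed values (log2 with a floor of 1), a 2-fold threshold, an estimated correlation and fry. Added after seeing the data were a fit without the 6 day 9 arrays and median scaling on the 12611 probes detected on every array. At most 37.7% of probes were detected on an array, so the array median over all probes lay among undetected probes. Comparisons were repeated over the 10 splits of each pair of groups, and over 100 drawn splits for the change between days. The fit and the list test were tried on simulated log2 values with known changes in place of PIP against NSB at day 11. Noise was drawn independently for each gene, and far fewer genes were shifted than changed in the real comparison. Normalization, filter, probe choice and correlation between genes were not part of the simulation, so its rates do not cover them. The fit recovered 62 of 67 genes shifted 1.5-fold, 67 of 67 shifted 2-fold and 66 of 66 shifted 4-fold, with 15 false calls (7.14% of calls). The list test called the 1 list shifted by 0.5 on the log2 scale and 1 of 25 others.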

Results

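Gene expression was measured in H9 cells, an established human embryonic stem cell line, during directed differentiation to placode, the thickened embryonic ectoderm that gives rise to lens, inner ear, anterior pituitary and cranial sensory neurons. Total RNA on 30 Illumina bead arrays fell into 10 groups of 3: day 1, day 3, and the arms that the labels call NSB and PIP at days 5, 7, 9 and 11. The labels call the 3 arrays of a group biological replicates and do not spell out NSB or PIP. Each of the 9 arrays of days 3 and 5 carries a pair of sample codes, and whether these stand for pooled RNA is not stated. As background from knowledge of the study, NSB denotes neural induction with Noggin, a BMP antagonist, and a blocker of activin and Nodal receptors, and PIP denotes a placode induction protocol that starts the same way. The median unnormalised signal per array ran from 45.4 to 74.7 intensity units, and 34.0% to 37.7% of the 48701 probes were detected. Across genes, arrays of a group correlated at 0.988 to 0.998, and the highest correlation between arrays of different groups was 0.994. Values below are log2 differences ± the standard error of the limma fit, with 3 arrays per group, over 13488 genes tested with 1 probe each. Where PIP is set against NSB, rose and fell mean higher and lower in PIP than in NSB on that day, not a change over days. The number of arrays limits their precision, and the offset added before the log makes the folds of dim probes smaller. A fold is given as "at least" where the probe was detected on no array of the dimmer group, and the log2 value beside it is the fitted one.

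The first principal component held 47.2% of the variance and ordered the arrays by day from 1 to 11. The second had its lowest scores at day 1 and the next lowest at day 9. The third held 9.92%, and the 6 arrays of day 9 had its lowest scores in both arms. The fourth held 6.85% and placed PIP above NSB at days 5, 7, 9 and 11. As a measured fact beside the day 9 values below, 8118 genes differed between day 9 and the mean of days 7 and 11 over both arms, 500 of them by at least 2-fold.

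**Figure D1:**
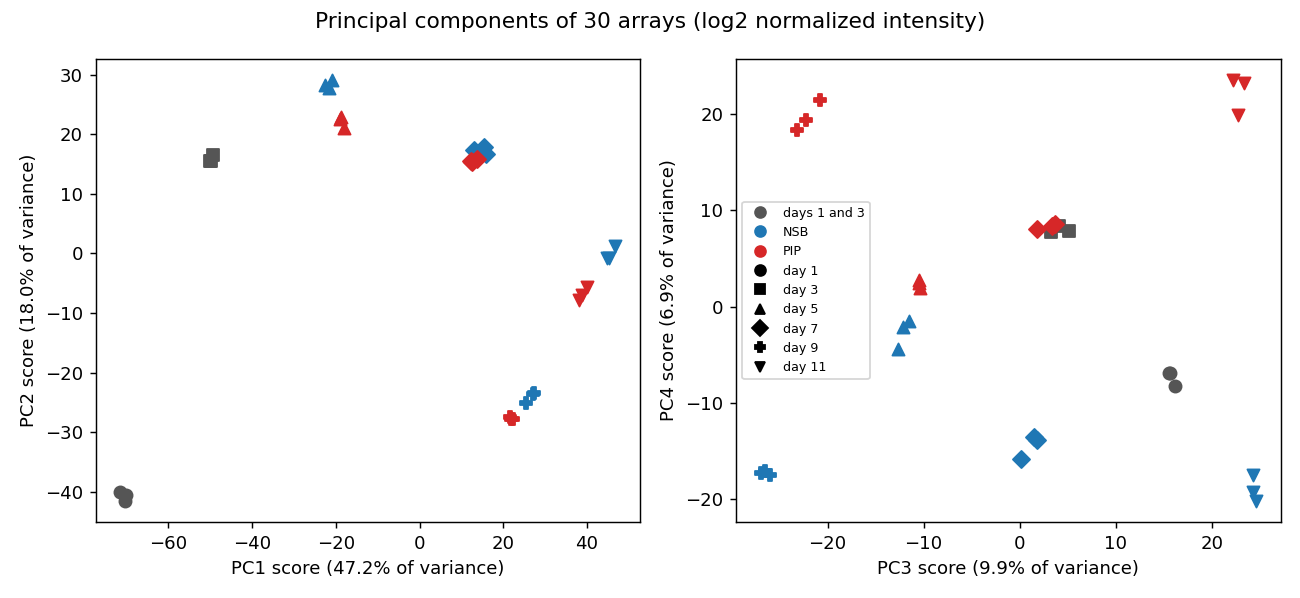
Scores of the 30 arrays on principal components 1 and 2 (left) and 3 and 4 (right), computed from log2 normalized intensities, with the share of variance on each axis. Each point is an array, colour gives the arm and shape the day, and the 6 day 9 arrays have the lowest scores on component 3.

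Between day 1 and day 3, before the labels part the arms, the Nodal pathway genes of the stem cell state went down. LEFTY1, a Nodal antagonist that Nodal itself induces, was at least 346-fold lower at day 3 (log2 -8.65 ± 0.11). The ligand NODAL was 59.8-fold lower (log2 -5.90 ± 0.10), with its probe detected on 1 of 3 arrays at day 3. NANOG, a core pluripotency factor, was 9.33-fold (log2 -3.22 ± 0.10) lower, and POU5F1 (OCT4) fell by 0.99 ± 0.09 on the log2 scale. IRX3, a transcription factor of the neural plate, was 24.2-fold higher and DLL1, a Notch ligand, at least 12.9-fold (log2 3.86 ± 0.08) higher. The other largest rises were CUZD1, at least 134-fold, NPTX1, at least 79.3-fold, RHBDL3, 55.6-fold, and GALNT9, at least 15.6-fold.

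Of the lists fixed beforehand, 8 of the 9 measured Nodal and activin targets fell and 1 rose (adjusted p = 2.25e-12), with SMAD7, a feedback inhibitor of the pathway, 29.8-fold lower and detected on 1 of 3 arrays at day 3. The pluripotency list followed with 12 of 19 lower, 3 higher and 4 not past the test (adjusted p = 1.20e-06). LEFTY1, LEFTY2, NODAL, TDGF1 and GDF3 were fixed as members of both lists, so these calls are not independent. Among FGF and ERK targets 10 of 14 fell and 2 rose (adjusted p = 3.58e-04), with ETV5 4.15-fold lower while EGR1, an immediate early gene, was 9.15-fold higher. Among hypoxia and glycolysis genes 10 of 14 fell and 2 rose (adjusted p = 0.0112, and adjusted p = 0.104 with an estimated correlation). Simple epithelial keratin and junction genes were higher in 10 and lower in 1 of 16 (adjusted p = 0.0102, and adjusted p = 0.127 with an estimated correlation), with CLDN3, a tight junction protein, 4.79-fold higher. Notch targets and ligands were higher in 9 and lower in 3 of 13 (adjusted p = 0.00879, and adjusted p = 0.103 with an estimated correlation). The remaining 20 lists were not called. Adjusted over the list alone, the counts were 2 up and 11 down for FGF and ERK targets, and those of the other lists named were as given. In all, 7341 genes changed, 3910 up and 3431 down, 1218 of them by at least 2-fold, and the values of 64.1% of genes did not overlap between the groups, where chance gives 10%. Scaling each array to its median in place of quantile normalization put 78.9% of the changed genes higher at day 3, against 53.3%, and median scaling on the probes detected on every array 36.4%.

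From day 3 to day 11 the NSB arm gained genes of the forebrain and eye field. LHX2, a transcription factor of both, was at least 212-fold (log2 8.12 ± 0.11) higher, RAX, an eye field factor, at least 56.7-fold (log2 6.26 ± 0.18) higher, and PAX6 at least 35.4-fold (log2 5.57 ± 0.09) higher. COL2A1, a collagen, and DACH1, a nuclear cofactor in eye development, were 74.8-fold and 54.1-fold higher, and LIX1 at least 36.8-fold higher. POU5F1 was 19.3-fold (log2 -4.27 ± 0.09) lower. The largest falls included CUZD1, at least 135-fold, NPTX1, 82.2-fold, the neuropeptide GAL, 66.3-fold, and RHBDL3, 62.6-fold, with these last 3 probes each detected on 2 of 3 arrays at day 11. SPP1 (osteopontin) was 37.7-fold lower.

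Of 19 measured anterior neural ectoderm genes 15 rose, 3 fell and 1 did not pass (adjusted p = 1.11e-08). Of 17 neural progenitor genes 14 rose and 1 fell (adjusted p = 6.31e-10), with FABP7, a fatty acid binding protein of radial glia, 27.6-fold higher. Notch genes rose in 9 and fell in 1 of 13 (adjusted p = 6.45e-04), with the Notch effector HES5 17.6-fold higher. BMP targets rose in 10 and fell in 1 of 13 (adjusted p = 0.00564), with ID4 4.18-fold and ID1 2.61-fold higher. FGF and ERK targets rose in 10 and fell in 2 of 14 (adjusted p = 0.00340, and adjusted p = 0.0677 with an estimated correlation). The pluripotency list had 13 of 19 lower and 0 higher (adjusted p = 2.20e-06). Simple epithelial genes were lower in 13 and higher in 1 of 16 (adjusted p = 4.03e-05), with the adhesion molecule EPCAM 7.88-fold lower, and cell cycle genes were lower in 12 and higher in 1 of 18 (adjusted p = 0.0339, and adjusted p = 0.265 with an estimated correlation). The counts adjusted over the list alone were as given except for 0 up and 14 down for pluripotency. In all, 8896 genes changed, 4221 up and 4675 down, 2429 of them by at least 2-fold. The values of 70.6% of genes did not overlap between the groups, against 10% by chance. OTX2, a forebrain factor, was 0.57 ± 0.10 higher but -0.16 under median scaling, which put 17.8% of the changed genes higher at day 11, against 47.4%, and median scaling on detected probes 62.0%.

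From day 3 to day 11 the PIP arm gained genes of non-neural ectoderm and of the anterior neural plate. TFAP2A, a transcription factor of non-neural ectoderm, was at least 70.9-fold (log2 6.26 ± 0.15) higher and DLX5, a homeobox factor of the neural plate border, at least 57.6-fold (log2 6.30 ± 0.11) higher. EYA1, a placode cofactor, was 11.7-fold (log2 3.55 ± 0.10) higher and LHX2 at least 139-fold (log2 7.52 ± 0.11) higher. COL2A1, 75.0-fold, and the sulfatase SULF1, at least 56.5-fold, were also among the largest rises. POU5F1 was 21.9-fold (log2 -4.45 ± 0.09) lower, and the largest falls were CUZD1, at least 140-fold, NPTX1, at least 83.4-fold, GAL, 60.4-fold, SCGB3A2, 40.7-fold, and ACTG2, 37.9-fold with its probe detected on 1 of 3 arrays at day 11.

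Of 13 non-neural ectoderm and border genes 10 rose and 2 fell (adjusted p = 6.16e-06), and each of the 5 measured sensory placode neurogenesis genes rose (adjusted p = 1.59e-04), with the neuronal factor ISL1 22.3-fold higher and detected on 2 of 3 arrays at day 3. The preplacodal and placode list rose in 8 and fell in 1 of 10 (adjusted p = 0.00570, and adjusted p = 0.0542 with an estimated correlation), with EYA2 2.90-fold higher. BMP targets rose in 12 of 13 with 0 lower (adjusted p = 6.76e-08), and trophoblast and amnion genes in 8 of 12 with 0 lower (adjusted p = 9.77e-04). Anterior neural ectoderm genes rose in 15 and fell in 4 of 19 (adjusted p = 3.32e-07), and neural progenitor genes rose in 14 and fell in 1 of 17 (adjusted p = 3.95e-09). Notch genes rose in 8 and fell in 2 of 13 (adjusted p = 0.0171, and adjusted p = 0.137 with an estimated correlation). Pluripotency genes fell in 13 and rose in 1 of 19 (adjusted p = 1.12e-06), and cell cycle genes fell in 14 of 18 with 0 higher (adjusted p = 0.00136, and adjusted p = 0.101 with an estimated correlation). Counts were 1 up and 14 down for pluripotency when adjusted over the list alone, and as given for the other lists named. In all, 8411 genes changed, 4097 up and 4314 down, 2116 of them by at least 2-fold. The values of 70.0% of genes did not overlap between the groups, against 10% by chance. Median scaling put 32.7% of the changed genes higher at day 11, against 48.7%, and median scaling on detected probes 55.2%.

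At day 11, transcripts of non-neural ectoderm, epithelial and sensory neuron genes stood higher in PIP than in NSB cells, and the forebrain factor PAX6 was high in both arms. TFAP2A was 41.0-fold (log2 5.36 ± 0.15) higher in PIP (adjusted p = 1.04e-20), and ISL1, a factor of cranial sensory neurons, was at least 20.4-fold (log2 4.94 ± 0.10) higher (adjusted p = 1.69e-23). CGA, the alpha subunit of pituitary and placental glycoprotein hormones, was 19.3-fold (log2 4.27 ± 0.24) higher, with its probe detected on 2 of 3 NSB arrays. POU4F1 (BRN3A), a sensory neuron factor, was 11.1-fold (log2 3.47 ± 0.12) higher and detected on 1 of 3 NSB arrays. PAX6 stood at 10.31 in PIP and 10.28 in NSB on the log2 scale, a difference of 0.03 ± 0.09 that did not pass the test (adjusted p = 0.842). Under median scaling on all probes the PAX6 difference was 0.39 and passed the same limma test (adjusted p = 0.0288), whereas it was 0.02 under median scaling on detected probes.

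The other largest rises in PIP were ALDH1A1, a retinoic acid synthesising enzyme, 16.2-fold (log2 4.02 ± 0.17) with 2 of 3 NSB arrays detected, TFAP2B, at least 10.4-fold (log2 3.70 ± 0.15), the matrix protein HAPLN1, 12.7-fold (log2 3.67 ± 0.11), PRDM1 (BLIMP1), 12.1-fold (log2 3.60 ± 0.16), EPAS1 (HIF2A), 10.6-fold (log2 3.40 ± 0.10), and the tight junction protein CLDN1, 9.37-fold (log2 3.23 ± 0.16) with 2 of 3 NSB arrays detected. The largest falls were smaller. IGFBP3 was 4.21-fold (log2 -2.07 ± 0.12) lower, TXNRD2 4.13-fold (log2 -2.05 ± 0.15) lower, the receptor VIPR2 at least 3.23-fold (log2 -1.97 ± 0.12) lower and FGF8, a ligand of the anterior neural ridge, 3.89-fold (log2 -1.96 ± 0.15) lower. SLC15A3, MEG3, GNG8, NDP and MPPED1 were between 3.29-fold and 3.71-fold lower, and ZIC4, a zinc finger factor of the dorsal neural tube, at least 2.40-fold lower.

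Non-neural ectoderm and border genes rose in 12 of 13 with 0 lower (adjusted p = 1.15e-20), with DLX3 3.95-fold (log2 1.98 ± 0.12), DLX5 4.46-fold (log2 2.16 ± 0.11) and GATA3 at least 4.05-fold (log2 2.51 ± 0.11) higher. Simple epithelial keratin and junction genes were higher in PIP than in NSB in 15 of 16 with 0 lower (adjusted p = 3.03e-18), with CLDN7 4.53-fold (log2 2.18 ± 0.11) and GRHL2, an epithelial transcription factor, at least 2.54-fold (log2 1.77 ± 0.11) higher. Within PIP this list did not gain from day 3 to day 11, with 4 higher and 6 lower of 16 (adjusted p = 0.526 by camera). KRT18 was 0.75 ± 0.09 higher by its brightest probe and -0.25 by its other probe. Sensory placode neurogenesis genes rose in 4 of 5 (adjusted p = 1.89e-04), while NEUROG2, a proneural factor, fell by 1.58 ± 0.16. Neural crest genes rose in 9 and fell in 1 of 14 (adjusted p = 2.93e-04), with ERBB3 4.34-fold and ETS1 3.77-fold higher. Trophoblast and amnion genes rose in 8 and fell in 1 of 12 (adjusted p = 1.12e-06), with CGA, HAND1, at least 4.31-fold, and VTCN1, at least 4.27-fold, higher. As measured facts beside the gains in ectoderm genes, CGA also stands in the pituitary list and HAND1 in the non-neural ectoderm list.

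Signalling readouts differed as well. BMP targets rose in 10 and fell in 1 of 13 (adjusted p = 6.01e-07), with BAMBI, a BMP-induced decoy receptor, 5.41-fold (log2 2.43 ± 0.09) and BMP4 3.56-fold (log2 1.83 ± 0.13) higher, and ID1 0.31 ± 0.08 higher but not past the test with the mean of its probes. WNT targets rose in 6 and fell in 1 of 12 (adjusted p = 7.04e-04), led by the secreted WNT inhibitor DKK1, 6.61-fold (log2 2.73 ± 0.17), and retinoic acid and HOX genes in 7 with 1 lower of 10 (adjusted p = 4.96e-05), with the retinoic acid degrading enzyme CYP26A1 3.18-fold (log2 1.67 ± 0.09) higher. FGF and ERK targets fell in 9 and rose in 1 of 14 (adjusted p = 1.34e-05), with ETV4 2.73-fold, IL17RD 2.88-fold and the ERK phosphatase DUSP6 2.40-fold lower. Notch genes fell in 7 and rose in 1 of 13 (adjusted p = 0.00168, and adjusted p = 0.0542 with an estimated correlation), with MFNG 2.82-fold lower.

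On the neural side, neuronal differentiation genes fell in 7 and rose in 1 of 15 (adjusted p = 0.00129), with MAP2, a neuronal microtubule protein, 2.14-fold (log2 -1.09 ± 0.10) lower. Anterior neural ectoderm genes fell in 9 and rose in 3 of 19 (adjusted p = 0.00764, and adjusted p = 0.0874 with an estimated correlation), with SIX3 2.21-fold (log2 -1.14 ± 0.14) lower and EMX2 2.23-fold (log2 1.16 ± 0.18) higher, and their median of -0.38 became 0.01 under median scaling. Neural progenitor genes fell in 6 and rose in 1 of 17 (adjusted p = 0.00218, and adjusted p = 0.0807 with an estimated correlation), with HES5 1.80-fold lower. Cell cycle genes fell in 3 of 18, 1 adjusted over the list alone (adjusted p = 0.0279, and adjusted p = 0.254 with an estimated correlation), and their median of -0.16 became 0.20 under median scaling. LHX2 fell by 0.61 ± 0.11 and did not pass under median scaling.

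The preplacodal and placode list was not called, with 3 of 10 higher, 4 lower and 3 not past the test (adjusted p = 0.622). Its members EYA1 and EYA2 were 6.60-fold (log2 2.72 ± 0.10) and 3.26-fold (log2 1.70 ± 0.15) higher in PIP, and SIX4 was 0.49 ± 0.08 higher, while DACH1, a neural progenitor gene as well, fell by 0.57 ± 0.09 and PAX8 by 0.67 ± 0.13. In the deposited processed values the falls of PAX8, DACH1, LHX2 and NEUROG2 did not pass the test. DACH1 did not pass under median scaling on all probes either (-0.16), whereas it was -0.53 under median scaling on detected probes. PITX1 and SOX1 were not analysed here, and SOX2 lay near the floor in every group, so it carries no information on the level of its transcript. POU5F1 (-0.19 ± 0.09, adjusted p = 0.138) did not pass, and PAX3, on 2 of 3 PIP arrays, was at least 1.03-fold higher but did not pass under median scaling on detected probes. The probe of NANOG was detected on 1 of 3 PIP arrays and 0 of 3 NSB arrays, so no difference is given for it. Of the other lists not called, epidermis had 4 higher and 1 lower of 7 (adjusted p = 0.0855), stress and apoptosis 5 and 1 of 16 (adjusted p = 0.160), mesendoderm 0 and 2 of 9 (adjusted p = 0.129), and lens 3 and 2 of 14 (adjusted p = 0.924). Mesenchyme and fibroblast genes were higher in 3 and lower in 3 of 11 (adjusted p = 0.935), endothelium and blood genes in 1 and 1 of 7 (adjusted p = 0.707), and Hedgehog targets in 0 and 1 of 3 (adjusted p = 0.263). Nodal and activin targets were higher in 2 and lower in 0 of 9 (adjusted p = 0.426). For 3 lists median and mean differed in sign, namely pluripotency, 4 higher and 3 lower of 19 (median -0.002, mean 0.05, adjusted p = 0.865), pituitary placode, 2 and 1 of 6 (median -0.03, mean 0.52, adjusted p = 0.629), and hypoxia and glycolysis, 1 and 4 of 14 (median 0.01, mean -0.06, adjusted p = 0.670).

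Adjusted over the list alone, the counts were 5 up and 4 down for pluripotency, 4 up and 4 down for preplacodal, 4 up and 2 down for lens, 1 up and 7 down for neural progenitor, 9 up and 3 down for neural crest, 1 up and 9 down for neuronal differentiation, 16 up and 0 down for simple epithelial genes, 4 up and 3 down for mesenchyme and fibroblast, 7 up and 1 down for WNT targets, 1 up and 10 down for FGF and ERK targets, 2 up and 7 down for Notch genes and 0 up and 1 down for cell cycle, and those of the other lists named were as given. In all, 3442 of 13488 genes changed at day 11, 1911 higher and 1531 lower in PIP, 432 by at least 2-fold with 321 higher and 111 lower. For 4773 genes (35.4%) the 3 values of the arms did not overlap, where chance gives 10%. The test called 14 lists, 8 up and 6 down, 10 of them also with an estimated correlation. Scaling each array to its median called 5628 genes, 94.3% of them higher in PIP against 55.5%, whereas median scaling on the 12611 probes detected on every array called 4154, 34.6% of them higher, so the split between rises and falls depended on the scaling.

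**Figure D2:**
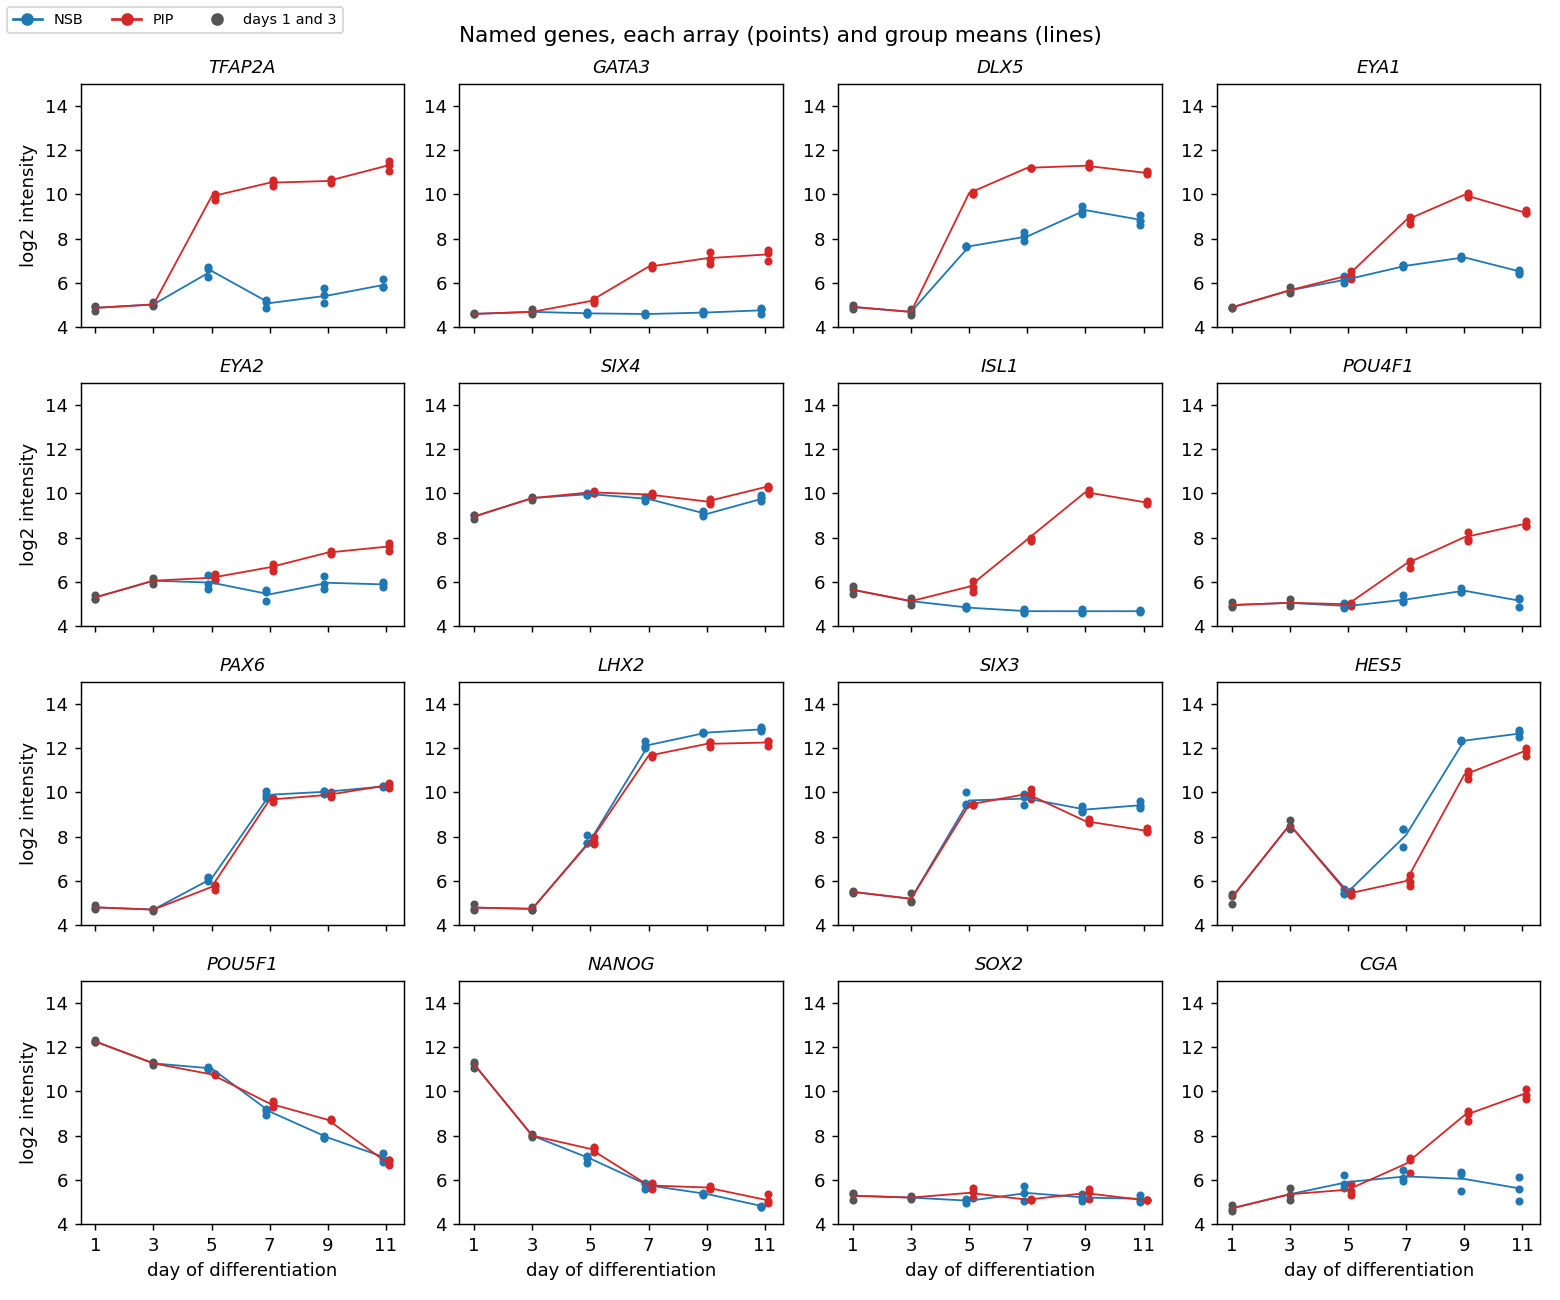
Log2 normalized intensity (vertical axis) by day of differentiation (horizontal axis) of 16 named genes, with a point for each array and lines through the group means, NSB in blue, PIP in red and days 1 and 3 in grey. TFAP2A, ISL1, EYA1 and CGA rise in PIP, PAX6 and LHX2 rise in both arms, and SOX2 stays near the floor throughout.

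At day 5, the first day on which the labels part the arms, non-neural ectoderm genes and BMP targets stood higher in PIP, and few differences reached 2-fold. TFAP2A was 10.3-fold (log2 3.37 ± 0.15) higher in PIP, DLX5 5.31-fold (log2 2.41 ± 0.11), and the BMP antagonist GREM1 4.84-fold (log2 2.28 ± 0.11). HAND1, a factor of extraembryonic and lateral tissues, was at least 3.82-fold (log2 2.12 ± 0.10) higher and ANKRD1 3.20-fold (log2 1.68 ± 0.11) higher. The largest falls were CUZD1, 5.52-fold, NPTX1, 4.43-fold, BMP2, a BMP ligand, 3.48-fold, FOXJ1, 2.63-fold, and SMOC2, 2.57-fold.

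Non-neural ectoderm and border genes rose in 9 of 13 with 0 lower (adjusted p = 6.90e-20). BMP targets rose in 7 of 13 with 0 lower (adjusted p = 6.20e-12), with ID1 2.09-fold (log2 1.07 ± 0.08) and ID4 2.86-fold (log2 1.52 ± 0.09) higher. The pituitary placode list fell in 2 of 6 with 0 higher (adjusted p = 7.97e-04), namely SIX6, 2.48-fold, which is also a forebrain and eye gene, and LHX4, 2.21-fold. Anterior neural ectoderm genes fell in 7 and rose in 1 of 19 (adjusted p = 0.00485, and adjusted p = 0.0719 with an estimated correlation), with SOX3 1.60-fold lower. The preplacodal and placode list of 10 measured genes was not called (adjusted p = 0.374). The counts adjusted over the list alone were as given except for 11 up and 0 down for non-neural ectoderm, 8 up and 0 down for BMP targets and 0 up and 3 down for pituitary placode. In all, 1554 genes changed, 800 higher and 754 lower, 45 by at least 2-fold. The values of 36.9% of genes did not overlap between the groups, against 10% by chance. The count fell to 875 without PIP day 5 replicate 1 and to 978 without NSB day 5 replicate 3, and rose to 3175 with array weights. Median scaling put 15.1% of the changed genes higher in PIP, against 51.5%, and median scaling on detected probes 62.9%.

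By day 7 non-neural ectoderm and epithelial genes stood higher in PIP, with the sensory neuron factor ISL1 and the placode cofactor EYA1. TFAP2A was 43.5-fold (log2 5.44 ± 0.15) higher with its probe detected on 1 of 3 NSB arrays, ISL1 at least 6.64-fold (log2 3.24 ± 0.10) higher, EYA1 4.17-fold (log2 2.06 ± 0.10) higher and GATA3 at least 2.91-fold (log2 2.14 ± 0.11) higher. HAPLN1, 13.6-fold, DLX5, 8.58-fold, and ERP27, 8.42-fold, were the other largest rises. The largest falls were CUZD1, 5.41-fold, IGFBP3, 4.35-fold, HES5, 4.23-fold, SEZ6, 3.71-fold, and LIMCH1, 3.17-fold.

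Non-neural ectoderm and border genes rose in 12 of 13 (adjusted p = 1.90e-32) and simple epithelial genes in 13 of 16 (adjusted p = 2.10e-20), with 0 lower in either list. KRT8 was 3.10-fold (log2 1.63 ± 0.11) higher, whereas KRT18 was 1.16 ± 0.09 higher by its brightest probe and -0.53 by its other probe. The further lists called upward were BMP targets, 9 of 13 (adjusted p = 1.66e-10), stress and apoptosis, 8 of 16 (adjusted p = 5.82e-05), WNT targets, 7 of 12 (adjusted p = 7.04e-04), and epidermis, 4 of 7 (adjusted p = 7.89e-04), each with 0 lower. Retinoic acid and HOX genes rose in 5 and fell in 1 of 10 (adjusted p = 1.78e-04), led by the retinoic acid receptor RARB, at least 3.74-fold, neural crest genes in 7 and 1 of 14 (adjusted p = 0.00122), and sensory placode neurogenesis genes in 2 and 1 of 5 (adjusted p = 6.12e-04). Lower in PIP were neural progenitor genes, 8 of 17 (adjusted p = 6.18e-06), neuronal differentiation genes, 5 of 15 (adjusted p = 0.00124), and mesenchyme and fibroblast genes, 4 of 11 (adjusted p = 1.89e-04), each with 0 higher. The preplacodal and placode list was not called, with 3 of 10 higher, 1 lower and 6 not past the test (adjusted p = 0.0919). VIM, an intermediate filament of neural progenitors, was 2.01-fold (log2 -1.01 ± 0.08) lower. Counts were 15 up and 0 down for simple epithelial genes, 9 up and 0 down for stress and apoptosis, 7 up and 2 down for neural crest, 1 up and 10 down for neural progenitor, 1 up and 6 down for neuronal differentiation, 1 up and 5 down for mesenchyme and fibroblast and 4 up and 2 down for preplacodal when adjusted over the list alone, and as given for the other lists named. In all, 1678 genes changed, 878 higher and 800 lower, 145 by at least 2-fold. The values of 23.9% of genes did not overlap between the groups, against 10% by chance. The count was 1081 under median scaling, which put 81.9% of changed genes higher against 52.3% (39.3% with median scaling on detected probes), 929 with array weights and 782 when only the arrays compared were fitted.

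At day 9 the same ectoderm, epithelial and sensory groups stood higher in PIP, and the trophoblast and amnion list was called as well. ISL1 was at least 28.4-fold (log2 5.38 ± 0.10) higher, TFAP2A 36.2-fold (log2 5.18 ± 0.15) with its probe detected on 2 of 3 NSB arrays, and HAND1 at least 12.1-fold (log2 4.22 ± 0.10). EYA1 was 7.08-fold (log2 2.82 ± 0.10) and CGA 7.30-fold (log2 2.87 ± 0.24) higher. HAPLN1, 14.4-fold, and RERG, at least 7.38-fold, completed the largest rises, and the largest falls were POU3F2 (BRN2), a neural factor, 5.00-fold, ZNF385B, 3.80-fold, IGFBP3, 3.39-fold, SORBS2, 3.20-fold, and TEK, an endothelial receptor, 3.08-fold.

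Non-neural ectoderm genes rose in 12 of 13 (adjusted p = 2.29e-27), simple epithelial genes in 15 of 16 (adjusted p = 2.92e-21) and retinoic acid and HOX genes in 6 of 10 (adjusted p = 4.20e-07), with 0 lower in each. BMP targets rose in 10 and fell in 1 of 13 (adjusted p = 8.46e-17), with ID1 5.94-fold (log2 2.57 ± 0.08) higher. Trophoblast and amnion genes rose in 8 and fell in 2 of 12 (adjusted p = 1.59e-04), sensory placode neurogenesis genes in 4 and 1 of 5 (adjusted p = 5.42e-04), and neural crest genes in 5 of 14 with 0 lower (adjusted p = 0.00153, and adjusted p = 0.0519 with an estimated correlation). Stress and apoptosis genes rose in 9 and fell in 2 of 16 (adjusted p = 0.0158, and adjusted p = 0.0588 with an estimated correlation), and epidermis genes rose in 2 of 7 with 0 lower (adjusted p = 0.0214, not called without the filter on dim probes). Lists lower in PIP were neural progenitor, with 11 lower and 2 higher of 17 (adjusted p = 9.57e-06), anterior neural ectoderm, 10 and 1 of 19 (adjusted p = 8.95e-05), neuronal differentiation, 7 and 0 of 15 (adjusted p = 0.0137), and Notch, 8 and 2 of 13 (adjusted p = 0.00879, and adjusted p = 0.103 with an estimated correlation). Hedgehog targets were lower in 2 of 3 with 0 higher (adjusted p = 0.0247, and adjusted p = 0.101 with an estimated correlation), hypoxia and glycolysis genes in 7 with 2 higher of 14 (adjusted p = 0.0269, and adjusted p = 0.158 with an estimated correlation), and FGF and ERK targets in 8 with 2 higher of 14 (adjusted p = 0.0339, and adjusted p = 0.180 with an estimated correlation). Adjusted over the list alone, the counts were 16 up and 0 down for simple epithelial genes, 9 up and 0 down for neural crest, 2 up and 10 down for anterior neural ectoderm, 1 up and 7 down for neuronal differentiation and 2 up and 8 down for hypoxia and glycolysis, and those of the other lists named were as given. In all, 2811 genes changed, 1392 higher and 1419 lower, 330 by at least 2-fold. The values of 36.9% of genes did not overlap between the groups, against 10% by chance. Median scaling put 37.8% of the changed genes higher in PIP, against 49.5%, and median scaling on detected probes 56.5%.

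**Figure D3:**
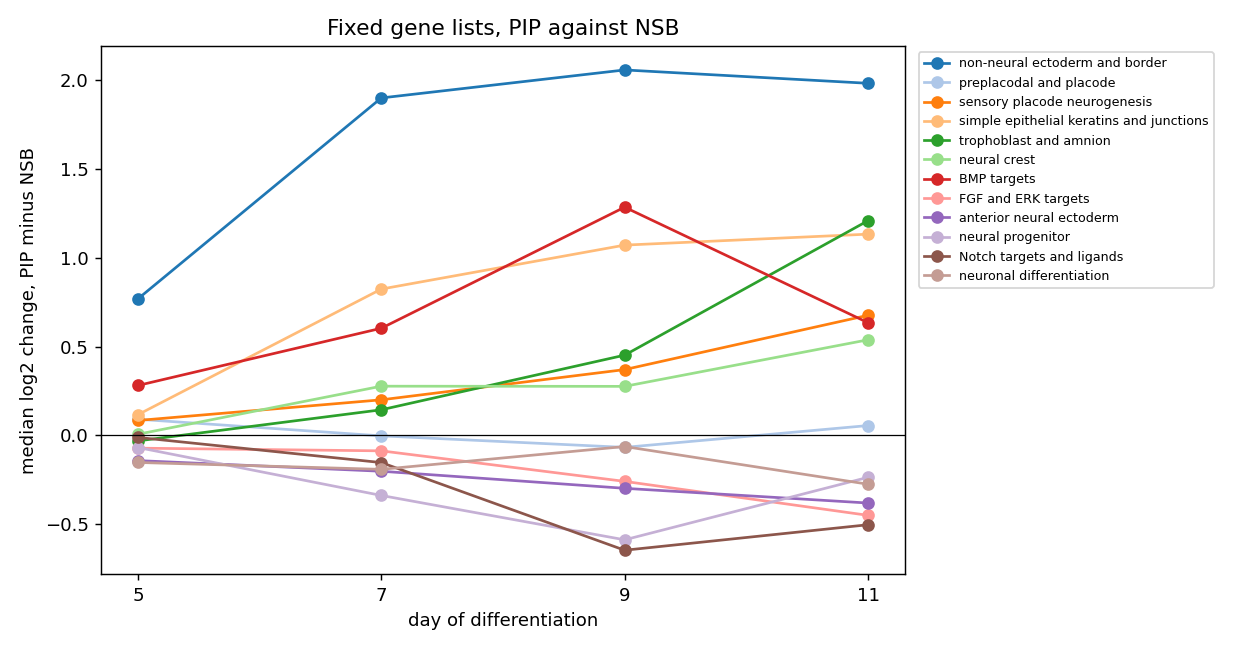
Median log2 difference of PIP minus NSB over the measured members of 12 gene lists (vertical axis) by day of differentiation (horizontal axis), with a line for each list. The non-neural ectoderm and border list is highest at each of the 4 days, at 1.98 on day 11, and the preplacodal and placode list stays near 0.

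This comparison asks how the difference between the arms developed over days. At days 9 and 11, 878 genes were higher in PIP on both days where independent draws of the same size would share 197, and 618 were lower on both where 161 would be shared, with 62 changed in opposite directions. For days 5 and 11 the numbers were 210 against 113, 184 against 85.6, and 146 opposite. At all 4 days 102 genes were higher in PIP, among them TFAP2A, DLX3, DLX5, GATA3 and MSX2, against 0.761 expected of independent draws, and 70 were lower, against 0.534. The 4 comparisons share each gene's estimate of spread from a single fit. Their calls are therefore not independent, and the excess over these expected numbers may be overstated. With day 9 left out, genes higher in PIP at every day numbered 110 and genes lower in PIP at every day 80. The PIP minus NSB difference itself changed from day 5 to day 11 for 2690 genes, 1547 upward and 1143 downward, 452 by at least 2-fold. CGA moved most, from -0.35 to 4.27 (change 4.62 ± 0.33, adjusted p = 3.00e-11), followed by NRP2, a semaphorin receptor, from -1.36 to 2.88 (change 4.24 ± 0.18), ALDH1A1 (4.03 ± 0.24), ISL1 (3.98 ± 0.15) and TFAP2B (3.62 ± 0.21). In the other direction moved DYNAP (-2.14 ± 0.15), TXNRD2 (-2.13 ± 0.22), FGF8 (-1.85 ± 0.22), the potassium channel KCNK12 (-1.84 ± 0.14) and MPPED1 (-1.74 ± 0.20, not past the test in the deposited processed values). Median scaling called 6248 genes for this change, 97.1% of them upward against 57.5%, and median scaling on detected probes 3467, 1076 upward and 2391 downward.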

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

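Chosen after the result was seen were the tests of signal over background, of normalization and of a separate run on day 9, of trophoblast or amnion cells, of ectoderm sharing their genes and of background correction of dim probes, and of dilution and of normalization of neural genes.

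The difference between PIP and NSB changed from day 5 to day 11 for 2690 genes. The genes below are the 44 that passed this test among 53 looked at, with the change on the log2 scale given for each. Those 53 were the largest PIP against NSB differences of single days and the panel, a choice that itself favours a change between days. DLX5, GREM1, SOX2, OTX2, POU5F1, NANOG, SOX10, SEZ6 and SORBS2 did not pass. Of 100 splits, the real one and others drawn with arrays exchanged between the arms within each day, 2 gave a count as large as 2690, the real one included. The other was the highest at 3300 and exchanged the whole arms at 1 day, which is a structure of the samples, and the next highest gave 1883. Such splits mix the arms, so they ask whether the arms differ at all. They cannot decide whether chance made the change between days. Upward moved the sensory, placode and border genes ISL1 (3.98), POU4F1 (3.39), TFAP2B (3.62), EYA1 (2.55), TFAP2A (1.99), GATA3 (1.96), EYA2 (1.48), HAND1 (0.57), PAX3 (0.59), DLX3 (0.50) and SIX4 (0.41). The probe of HAND1 was detected on no NSB array at day 5 or day 11, and that of PAX3 lay near the floor at day 11. The sizes of these 2 changes are therefore uncertain. Upward moved as well CGA (4.62), ALDH1A1 (4.03), EPAS1 (3.28), BMP2 (3.09), CLDN1 (3.07), SMOC2 (2.81), HAPLN1 (2.69), CUZD1 (2.45), PRDM1 (2.29), FOXJ1 (2.04), NPTX1 (1.74), ERP27 (1.41), RERG (0.88), KRT18 (0.51) and PAX6 (0.41). For BMP2, SMOC2, CUZD1, FOXJ1, NPTX1 and PAX6 the upward change started from a lower level in PIP at day 5. The probe of CUZD1 was detected on no day 11 array of either arm, and that of NPTX1 on no PIP array at day 11. Their upward changes are thus not gains in PIP. Downward moved the neural and signalling genes FGF8 (-1.85), ZIC4 (-1.41), NDP (-1.46), POU3F2 (-0.80), HES5 (-0.77), LHX2 (-0.57) and ID1 (-0.76). Downward moved also TXNRD2 (-2.13), MPPED1 (-1.74), TEK (-1.65), MEG3 (-1.63), VIPR2 (-1.54), SLC15A3 (-1.50), ZNF385B (-1.37), IGFBP3 (-1.28), GNG8 (-1.15), ANKRD1 (-1.08) and LIMCH1 (-0.74). Of these movers, ID1 and ANKRD1 were higher in PIP at all 4 days, so their difference was smaller at day 11 than at day 5 without turning in sign. The difference of ID1 was larger at day 9 than at day 5 or day 11. At day 11 it did not pass the test with the mean of its probes.

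Among 6005 detected probes with no gene name, which the gene comparisons did not use, 678 changed between PIP and NSB at day 11, 273 higher and 405 lower, by the same limma test.

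At day 9 both arms stood apart from days 7 and 11, with 8118 genes different from the mean of those days, 4042 higher and 4076 lower. The 3-of-9 splits in each arm gave 5815 genes for the real split, and 1 of 100 splits, the real one, was as large, with 3046 as the highest other. Those others were drawn at random across days 7, 9 and 11, which puts differences between days into the spread. Whether day 7 or day 11 would stand apart as much was not tested, so the splits do not single out day 9. Argued against was a difference in signal over background, since 0 of the 6 day 9 arrays had a share of detected probes (34.7% to 35.6%) outside the range of the 12 others (34.0% to 36.2%), and also between-array normalization as the whole cause, since 92.0% of the 8118 genes stayed past the threshold in the same direction under median scaling on detected probes and 80.8% under median scaling on all probes. A separate culture or array run on day 9 may account for the shift and cannot be told apart from a change on that day, because the shifts of both arms correlated at 0.860 across genes, which are not independent replicates, and day and run are not parted by the labels. A stage passed through on day 9 by both arms stays open, untested.

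Trophoblast and amnion genes stood higher in PIP at day 11, where 8 of 12 rose, and 2 of those 8 also stand in an ectoderm or placode list. Argued against was background correction of dim probes as the cause, since 8 of the 8 stayed past the threshold without background correction. Trophoblast or amnion cells among the PIP cells and ectoderm that shares these genes cannot be told apart, since 2 of the 8 were already higher at day 7 (7 at day 9) and no label separates the cells. Of a further list of 20 trophoblast and amnion genes 11 were measured, 4 of which stand in the ectoderm and epithelial lists, and the other 7 rose as a set (6 higher, 0 lower, median 0.69, p = 2.146e-08 by camera, and p = 1.21e-05 with an estimated correlation), with 1 of them higher at day 7 already. Levels do not part the explanations either, since KRT19 (12.04 in PIP and 11.21 in NSB, on the log2 scale) and TFAP2C (9.27 and 7.48) were present in both arms, the others lay between 5.39 and 6.75 in PIP, KRT7 (5.49) did not pass (adjusted p = 0.0619), CGA of the fixed list reached 9.87, IGFBP3 fell by 2.07, and the labels name no sort.

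Neural genes were lower in PIP at day 11 while many stayed, as of 25 that had risen at least 2-fold over the mean of both arms 12 were lower, 3 higher and 10 neither. Under median scaling on detected probes 12 of the 12 stayed lower. This scaling put the median difference of all genes at -0.10, so it could hardly undo a fall. Median scaling on all probes, whose array median lay among undetected probes, put the median difference of all genes at 0.28, and 6 of the 12 stayed lower. In the deposited processed values 8 did. Between-array normalization as the whole cause is thus argued against for those 6 genes alone, and for the others it stays open. The same neural cells diluted by other cells that lack these genes would lower each of these genes alike. However, 3 were higher in PIP, namely EMX2 (1.16), NR2F1 (0.62) and CXCR4 (0.33). These values argue only against dilution by cells that lack all of these genes. Dilution by cells that express those 3 cannot be told apart, as no label separates the cells. A different regional identity of the neural cells in PIP stays open as a hypothesis that was not tested.

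For each comparison of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real count of genes and the highest other were 7341 and 0 for day 3 against day 1, 8896 and 0 for NSB and 8411 and 0 for PIP from day 3 to day 11, and for PIP against NSB 1554 and 0 at day 5, 1678 and 20 at day 7, 2811 and 1 at day 9, and 3442 and 20 at day 11, with 1 split as large in each. For called lists they were 6 and 5 (1 split as large), 8 and 10 (3 splits), 10 and 13 (3 splits), 4 and 6 (2 splits), 12 and 8, 16 and 9, and 14 and 9 (1 split each), in the same order of comparisons.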

How the results depend on the processing

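Median scaling on detected probes and the fit without the day 9 arrays were added after seeing the data, and the other alternatives were planned. Of 13693 values of named genes under the alternatives, 514 of genes called with the main processing no longer passed and 9 turned in sign. Among genes not called there, 56 values newly passed in the same direction. The other 13114 counted as kept, which for genes not called includes any that turned in sign, as these were not counted apart. Of 1190 values of called lists 1157 kept direction and side of the threshold and 33 no longer passed. Of these 33, 19 came with the estimated correlation, under which 51 of the 70 lists were kept. Direction and side were kept by all 70 lists with fry, without background correction, with the replicate block and in the deposited processed values. With fry this says little, as fry called more lists than camera in every comparison. Signal over background limits dim probes, whose folds are compressed, and at day 11 the probes of SOX2, NANOG and PAX3 lay near the floor.

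Counts moved by over 1.5 times as follows, and the cause was not tested except where a threshold or a smaller set of arrays made it. At least 2-fold were 1218 genes for day 3 against day 1, 2429 for NSB and 2116 for PIP from day 3 to day 11, 45, 145, 330 and 432 for PIP against NSB at days 5, 7, 9 and 11, and 452 for the change between days. Median scaling gave 1081 genes at day 7, 5628 at day 11 and 6248 for the change. The median log2 difference of all genes lay between -0.02 and 0.02 with quantile normalization. It was 0.20, -0.43, -0.16, -0.15, 0.09, -0.09, 0.28 and 0.45 with median scaling, in the order of comparisons just used, and -0.17, 0.20, 0.10, 0.03, -0.07, 0.03, -0.10 and -0.11 with median scaling on detected probes, so the ratio of rises to falls follows the scaling. Array weights, whose estimation stopped before full convergence, gave 3175 genes at day 5 and 929 at day 7, and only the arrays compared gave 782 at day 7. With an estimated correlation 3 lists were called for day 3 against day 1 and 10 at day 9. Fry called 22, 21 and 23 lists in the first 3 comparisons, and 12, 21 and 22 at days 5, 7 and 11. Among called genes, those that turned under median scaling were OTX2 in NSB (-0.16), CDK1 (0.0650) and AURKA (0.17) at day 11, and CRMP1 (0.0150) and KDM3A (0.0557) for the change. Turned on detected probes were HBG2 at day 3 (-0.0460), ISL1 in NSB (0.18), NANOG at day 11, a probe at the floor, (-0.0625) and ENG for the change (-0.12).

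Leaving out 1 array at a time gave 6593 to 6886 genes for day 3 against day 1, 8388 to 8591 for NSB, 7855 to 7985 for PIP, 875 to 1171 at day 5, 1280 to 2435 at day 7, 2131 to 2545 at day 9, 2759 to 3182 at day 11 and 2237 to 2705 for the change, and 6 to 9, 8 to 8, 10 to 11, 4 to 5, 12 to 15, 15 to 16 and 13 to 14 lists. At day 5 the count fell by over 1.5 times without PIP replicate 1 (875) and without NSB replicate 3 (978). Without the day 9 arrays 3346 genes changed at day 11. A block on the slide was not run, since slides are not named in the table used here.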

Other observations

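The comparison of day 9 with days 7 and 11 was chosen after its result was seen. Genes that stood higher at day 9 in both arms included VGF, a secreted neuronal peptide precursor, by 2.94 on the log2 scale, SNAP25, a synaptic vesicle fusion protein, by 2.43, ANXA1, an annexin, by 2.51, ARHGDIB by 2.51, KITLG, the ligand of KIT, by 2.31, and WNT2B by 2.42. Genes that stood lower included the proneural factor NEUROG2 (-2.64) and LDB2 (-2.44). Also lower were TXNIP (-2.32) and ARRDC4 (-2.13), both genes that respond to glucose through the same transcription factors. FGF and ERK targets were higher in 9 and lower in 1 of 14 (adjusted p = 0.0113 by camera, and adjusted p = 0.186 with an estimated correlation), and hypoxia and glycolysis genes in 9 and lower in 2 of 14 (adjusted p = 0.0113, and adjusted p = 0.186 with an estimated correlation). Values are differences of day 9 from the mean of days 7 and 11, averaged over the arms with 3 arrays per group.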
